A study of Mus musculus with 16 samples.

How the data were processed

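Expression was measured in 16 mouse samples on Affymetrix U74Av2 arrays, 1 array per sample: 12 arrays of embryonic stem (ES) cell lines in 4 groups of 3, and 4 arrays of liver in 2 groups of 2. Per the labels, the authors isolated total RNA, followed the manufacturer's protocol and processed the arrays with MAS5.0 at its default settings. The deposited values are the resulting signal of each probe set, a linear intensity, and the authors had scaled each array, since the 2% trimmed mean of the deposited signal was 1501 or 1502 in all 16 arrays. The table holds no detection calls and no controls other than the probe sets of the array itself. All 16 columns were used, and groups were taken from the sample labels. The labels give no replicate numbers, so replicates carry the order in which the samples are listed and were never paired.

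Signals were rescaled so that the 2% trimmed mean of each array is 500, a pseudocount of 32 was added and log2 was taken. Probe sets with a mean rescaled signal of at least 100 over the arrays of a fit were tested, and control probe sets were left out of the tests. Of 12488 probe sets, 10855 map to 1 gene, 396 to several and 1237 to none in the annotation of the array, and together the single-gene ones cover 8252 genes. A gene was represented by its probe set with the highest mean signal. Gene order and chromosomes came from a reference gene table of GRCm38.p6; probe positions within a gene are not given in the sources used here.

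Group means were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The 4 ES groups were fitted together (7349 probe sets, 8 residual degrees of freedom), the livers alone (7160 probe sets, 2 residual degrees of freedom), and the Abca1 +/- and ESVJ ES groups with both liver groups for the comparison of tissues (7883 probe sets). The comparisons were Abca1 +/- against ESVJ, Cdk4 +/- against E14, livers labelled Abca1 +/- against +/+ livers, E14 against ESVJ, the difference of both ES mutation effects, and the difference of the Abca1 effect between ES cells and liver. P-values were adjusted by Benjamini and Hochberg over all probe sets of a comparison, with a threshold of 0.05, and "passed" refers to this threshold. Single probe sets of Abca1 and Cdk4 were also compared with two-sided exact permutation tests.

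Of 40 gene lists written before the data were examined, 22 had at least 5 measured members in the ES comparisons and 33 in liver; they were tested with camera at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. The same test was applied to 20 chromosomes with at least 20 genes each, where a shift of at least 0.1 was also required. Members of a list were counted after adjustment over all probe sets and after adjustment over the list alone.

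The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named are Abca1 and Cdk4; per comparison the 10 genes with the largest rise and the 10 with the largest fall among those that passed, have a single symbol and do not overlap between the groups; where fewer than 5 passed, the 10 with the smallest unadjusted p; up to 4 members per described list with the smallest p; the 5 genes with the largest difference in each direction for interactions and for E14 against ESVJ; and the measured neighbours of Abca1 and Cdk4. The probe sets without a single gene in the Abca1 ES comparison, the values of single livers and the ratios of the RNA controls were chosen after the data were seen.

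The tests were tested on simulated data built from the mean and the spread of each probe set, with 200 probe sets changed at 4 sizes. The noise was independent between genes, which real arrays do not have, so the list tests fare better there than on real data. A change of 1 on the log2 scale was found in 86% of cases in both ES comparisons and in 16% in liver, and a change of 2 in 100% and 76%. A shift of 0.3 in a list was found in the ES comparisons (adjusted p = 4.4e-23 in the Abca1 one) and missed in liver (adjusted p = 0.209), with 0 other lists called. Outside the 200, 3 probe sets were called in the Abca1 ES comparison, 11 in the Cdk4 one and 3 in liver. The number of arrays and the spread between them, not a read depth, limit the precision: the median standard error of a log2 change was 0.17 in ES cells and 0.38 in liver.

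Alternatives were the deposited scale, quantile normalization, pseudocounts of 1 and 100, no signal filter or one of 200, no intensity trend, leaving out probe sets marked for cross-hybridisation, the mean of all probe sets of a gene, an estimated correlation, fits of only the 2 compared groups or of all 16 arrays, and leaving out each array in turn. Arrays with a high signal of the BioB hybridisation control (replicate 1 of Abca1 +/-, replicate 3 of ESVJ and replicate 2 of Cdk4 +/- ES cells) were taken as a block or left out, an alternative chosen after seeing the data.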

Results

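RNA from 16 mouse samples in 6 groups was measured on mouse U74Av2 arrays, 1 array per sample. Embryonic stem (ES) cells made up 4 groups of 3 arrays each. They were a line with 1 copy of Abca1 mutated (Abca1 +/-), its +/+ parental line ESVJ, a line with 1 copy of Cdk4 mutated (Cdk4 +/-), and the +/+ line E14 that the labels give as its control. Livers made up 2 groups of 2 arrays each, from +/+ mice and from mice labelled Abca1 +/-, with C57BL6/J and 129/SvJ mixed in their background. The Abca1 +/- and ESVJ cells grew on feeder cells, which were removed before RNA isolation, while the E14 and Cdk4 +/- cells grew without feeders. The labels give no order or pairing of the arrays of a group and do not say whether they come from separate cultures, so every p measures only the spread between these samples. Signals are MAS5 intensities, rescaled so that the trimmed mean of each array is 500, and the median signal per array then lay between 126 and 170. Log2 changes and folds are on the scale of log2(signal + 32), which understates the change of genes with low signal. The number of arrays and the spread between them limit the precision: the 95% interval of a typical change spanned 0.37 on either side on the log2 scale in ES cells and 0.85 in livers. Across all probe sets, arrays of the same ES group correlated with r from 0.970 to 0.990 and arrays of different ES groups with r from 0.9255 to 0.986. The mean r was 0.981 between Abca1 +/- and ESVJ arrays and 0.979 among ESVJ arrays. The +/+ livers correlated with r = 0.968 and the livers labelled Abca1 +/- with r = 0.937. Livers of different groups correlated with r from 0.900 to 0.962, and ES arrays with liver arrays with r from 0.580 to 0.635.

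The first comparison asks what the loss of 1 copy of Abca1, the transporter that moves cholesterol out of cells to apolipoproteins, does to ES cell transcripts. Abca1 itself was at a signal of 110 ± 14.8 (SD, n = 3) in Abca1 +/- cells and 141 ± 38.1 (SD, n = 3) in ESVJ cells by the first of its 2 probe sets. Its log2 difference was -0.26 (SE 0.20, adjusted p = 0.9997), and its level as a share of the control had a 95% interval from 62.0% to 112%, which includes no difference. The second Abca1 probe set stayed below the signal filter at 96.6 ± 33.3 (SD, n = 3) and 110 ± 17.4 (SD, n = 3). Of the 6 nearest measured neighbours of Abca1 on chromosome 4, Pgap4 was at -0.17, Rnf20 at -0.15, Smc2 at -0.34, Slc44a1 at -0.07, Tmem38b at -0.09 and Rad23b at -0.07 (adjusted p = 0.9997 for each). Of 7349 probe sets, 1 rose and 1 fell, neither of them tied to a single gene in the annotation. The one that rose did so 2.76-fold, from 377 ± 68.6 to 1089 ± 60.1 (SD, n = 3 per group, adjusted p = 7.01e-04), and the other fell from 164 ± 13.4 to 45.5 ± 8.40 (adjusted p = 0.0391).

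No named gene passed the test in Abca1 +/- ES cells, and the 10 with the smallest unadjusted p are given as values. Krt8 and Krt18, which encode partner keratins of simple epithelia, had log2 differences of 0.50 (SE 0.11, adjusted p = 0.777) and 0.55 (SE 0.12, adjusted p = 0.783). Esrrb, an orphan nuclear receptor of the pluripotency network, had -0.90 (SE 0.24), and Lmnb1, which encodes the nuclear lamina protein lamin B1, had -1.16 (SE 0.31). Cd99, a cell surface glycoprotein gene, had 0.66, Tgfb1i1, a focal adhesion adaptor gene, had 0.61, and the RNA-binding protein gene Rbm4b had -0.84. Pdcd4, an inhibitor of translation initiation, had -0.58, Mtf2, a component of Polycomb complexes, had -0.70, and the corepressor gene Tle5 had -0.55, with adjusted p of 0.974 or more for these 8 genes. The cholesterol transport list had 18 measured members, among which Pltp and Srebf1 were at 0.17 and -0.13, and the cholesterol synthesis list had 16, among which Cyp51 was at -0.31; none of these members passed. In the list of primitive and visceral endoderm genes, 0 of 20 measured members passed over all genes and 2, Krt8 and Krt18, were higher when adjusted over the list alone. None of 22 gene lists passed with camera (smallest adjusted p = 0.524, 1 at unadjusted p under 0.05), and none with an estimated correlation or with fry. At unadjusted p under 0.05 limma counted 241 probe sets, fewer than the 367 that chance gives, and 583 probe sets (7.93%) had no overlap between the groups, where chance gives 10%. In simulated data of the same size 86% of changes of 1 on the log2 scale and 28% of changes of 0.5 were found. Without any 1 of the 6 arrays a single probe set passed, with all 16 arrays in one fit none did, and the feeder cell markers did not pass as a list (median -0.05, adjusted p = 0.524).

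**Figure D1:**
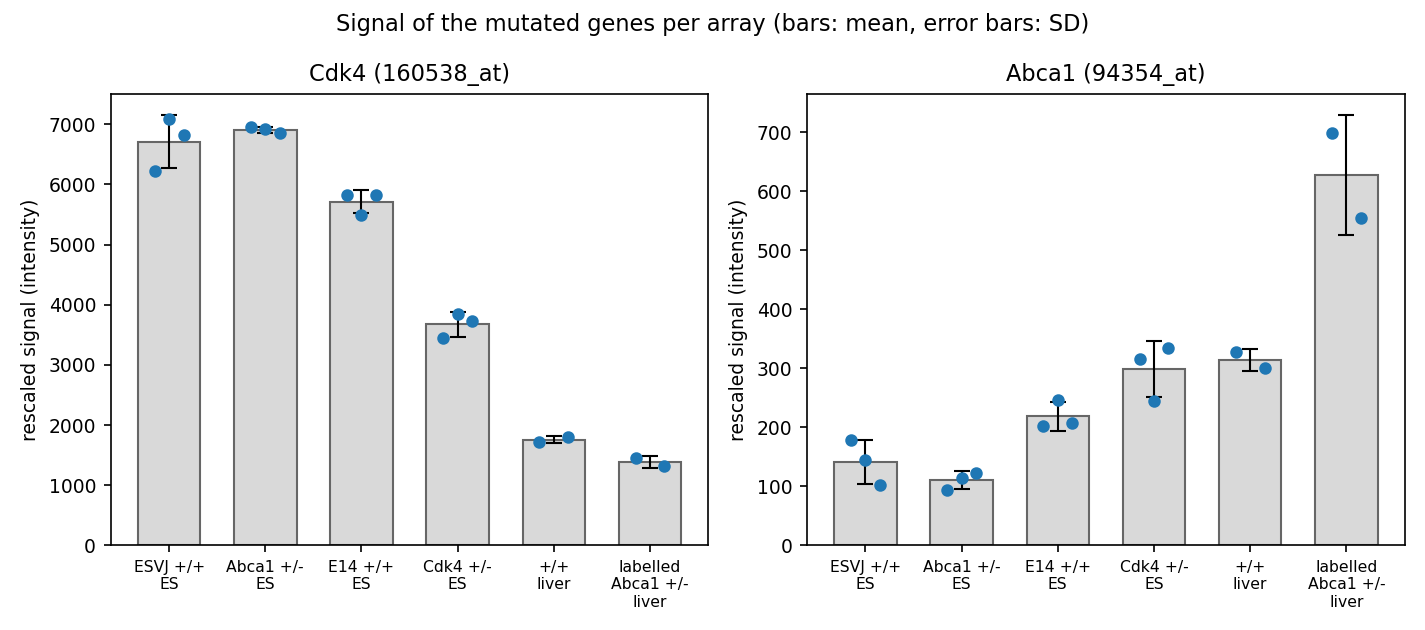
Rescaled signal (intensity) of Cdk4 and Abca1 in each array (points) with the mean (bars) and SD (error bars) of the 6 groups. The 3 Cdk4 +/- arrays lie between 3448 and 3854 for Cdk4, below the E14 arrays, and for the first Abca1 probe set, the one shown, both livers labelled Abca1 +/- lie above the +/+ livers.

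The second comparison asks what the loss of 1 copy of Cdk4, the cyclin D-dependent kinase that drives passage through G1, does to ES cell transcripts. Cdk4 fell in Cdk4 +/- cells, from 5716 ± 189 to 3678 ± 209 (SD, n = 3 per group) by its probe set of higher signal. This is 64.5% of the E14 level (95% interval 55% to 75%), a log2 change of -0.63 (SE 0.10, adjusted p = 0.00436), and the second probe set was at -0.70 (SE 0.24, adjusted p = 0.104). A two-sided exact permutation test of either probe set gave p = 0.1, the smallest that 3 against 3 arrays allow. Of 7349 probe sets, 190 rose and 171 fell, 39 of them by 2-fold or more, and the 361 changed probe sets covered 319 named genes. On this scale the largest rise of a named gene was that of Trib3, a stress-induced pseudokinase, from 188 ± 114 to 740 ± 296 (SD, n = 3 per group, 3.62-fold, adjusted p = 0.0121). This call was lost without E14 replicate 2 or Cdk4 +/- replicates 1 or 3 (adjusted p = 0.0575, 0.0619 and 0.0644). The largest fall on this scale was that of Hspa1b, an inducible heat shock protein of the Hsp70 family, from 743 ± 261 to 241 ± 15.7 (SD, n = 3 per group, a log2 change of -1.46, adjusted p = 0.00436). Both ranks depend on the pseudocount: with 100, Hspa1b was at -1.263 and Ppan at -1.275.

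Among the other 9 genes with the largest rises in Cdk4 +/- cells, Txnip, which encodes a thioredoxin-binding arrestin, rose 2.70-fold (SE 0.13 on the log2 scale) by 1 probe set and was at -0.05 by its other. Klf10, a zinc finger gene induced by TGF-beta, rose 2.67-fold (SE 0.14), and Stat6, the transcription factor of interleukin-4 signalling, rose 2.32-fold (SE 0.14). Tnc, which encodes the matrix protein tenascin C, rose by 1.13 on the log2 scale (SE 0.21), Clip3, a linker protein gene, by 1.33 (SE 0.27), and Ap5s1, a subunit of an endosomal adaptor, by 1.46 (SE 0.36). Their E14 signals were 36.5, 52.5 and 42.9, and with a pseudocount of 1 Ap5s1 was at 2.19, above Trib3 at 2.06. Among the largest falls, Ppan, a ribosome assembly factor, fell by 1.37 (SE 0.16), and Gclm, the modifier subunit of glutathione synthesis, fell by 1.28 (SE 0.16) on the log2 scale. Socs1, a suppressor of cytokine signalling, fell by 1.24, Cbr3, a carbonyl reductase, fell by 1.12, Ubac2 fell by 1.15 and Epb41l4aos fell by 1.09. Ina, which encodes the neuronal filament protein internexin, fell by 1.04, and the transcription factor gene Yy1 fell by 0.96. These 14 genes had adjusted p between 7.82e-05 and 0.0498. Leaving out 1 array ended the calls of Ap5s1 (4 of 5 arrays), Ubac2 (3 of 4), Pou3f1 (4 of 6), Trib3 (3 of 6) and Clip3, Tnc and Atf3 (2 of 6 each). All 7 lost their call without Cdk4 +/- replicate 1, and the lost calls had adjusted p from 0.0502 to 0.1498. The other 13 of the 20 genes passed each time. Ubac2 also did not pass under 5 other settings, such as quantile normalization (adjusted p = 0.0612), nor Ap5s1 without a filter (adjusted p = 0.0592). In Abca1 +/- cells none of the 20 genes passed. For 9 of the 20 the difference between both comparisons itself passed, which the choice of the genes by their Cdk4 change favours.

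**Figure D2:**
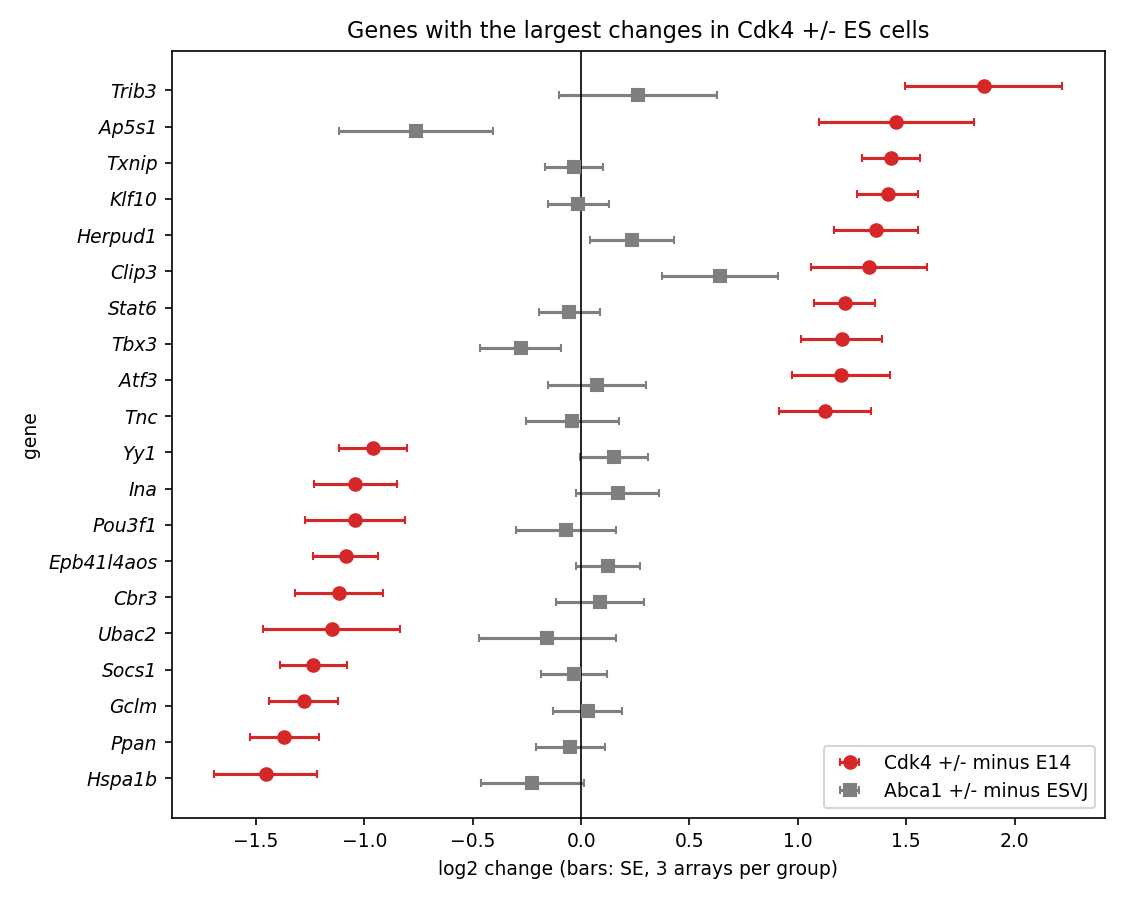
Log2 change (x axis, bars give the SE, 3 arrays per group) of the 20 genes with the largest changes in Cdk4 +/- ES cells, in the Cdk4 comparison (circles) and in the Abca1 comparison (squares). The genes were chosen by their change in the Cdk4 comparison, so smaller values in the other one follow in part from that choice.

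By list, 4 of 36 measured pluripotency genes rose in Cdk4 +/- cells, none fell and 32 did not pass; adjusted over the list alone, 8 rose and 1 fell. The 4 were Tbx3, a T-box factor of ES cell self-renewal (log2 1.20, SE 0.19), and the core factors Klf4 (0.79, SE 0.14), Sall4 (0.63, SE 0.13) and Nanog (0.62, SE 0.16). The list median was 0.21 with 0.02 for the other genes (camera adjusted p = 0.00245), and adjusted p = 0.418 with an estimated correlation. Of 18 genes of the interferon and MHC class I list, 3 fell, none rose and 15 did not pass; adjusted over the list alone, 1 rose and 6 fell. These were the immunoproteasome subunits Psmb8 (-0.92, SE 0.23) and Psmb10 (-0.72, SE 0.18) and the class I heavy chain gene H2-D1 (-0.56, SE 0.14). The list median was -0.30 (adjusted p = 0.00326), and adjusted p = 0.418 with an estimated correlation. In the unfolded protein response and ATF4 list 4 of 27 measured members rose and none fell, and 6 rose and 2 fell when adjusted over the list alone. They were Herpud1, an endoplasmic reticulum stress protein gene (1.36, SE 0.19), the transcription factors Atf4 (0.94, SE 0.14) and Atf3 (1.20, SE 0.23), and Trib3. The list itself did not pass (median 0.18, adjusted p = 0.0673). It passed without E14 replicate 3 (adjusted p = 0.00104, and adjusted p = 0.172 with an estimated correlation) or Cdk4 +/- replicate 2 (adjusted p = 0.0278, and adjusted p = 0.510 with an estimated correlation). Without 1 array at a time Tbx3, Klf4, Herpud1 and Atf4 passed each time, Sall4 and Atf3 in 4 of 6 cases, Trib3 in 3, Psmb8 and Psmb10 in 2, Nanog in 1 and H2-D1 in 0 (adjusted p from 0.0504 to 0.118). No list passed with an estimated correlation, where 2 were at unadjusted p under 0.05, and 4 of 22 passed with fry: pluripotency, interferon and MHC, neuroectoderm and mitosis.

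Among cell cycle genes, Prc1, a spindle midzone protein gene (0.85, SE 0.13), and Smc2, a condensin subunit gene (0.77, SE 0.16), rose, the only 2 of 35 mitosis genes that passed over all genes (4 rose adjusted over the list alone). Of 38 S phase genes, the flap endonuclease gene Fen1 (-0.57, SE 0.15) and the origin recognition gene Orc1 (-0.43, SE 0.11) fell and 36 did not pass (2 fell adjusted over the list alone). In the list of G1 cyclins, kinases and inhibitors, Cdk4 was the single member of 21 that changed, by both adjustments; cyclin E1 gene Ccne1 was at -0.50 (SE 0.19, adjusted p = 0.140). Of 13 p53 response genes 1 rose by either adjustment, the growth arrest gene Gadd45a (1.02, SE 0.11). Of 20 neuroectoderm genes, En2 (0.78, SE 0.15) and Nnat (1.08, SE 0.23) rose and Pou3f1, a POU factor of neural lineages, fell (-1.04, SE 0.23), by either adjustment. In the cholesterol synthesis list Hmgcs1, an early enzyme, fell (-0.87, SE 0.23), 1 of 16 by either adjustment. The list median was -0.21 (adjusted p = 0.123). It was -0.48 without E14 replicate 3 (adjusted p = 2.25e-04, and adjusted p = 0.225 with an estimated correlation) and -0.38 without Cdk4 +/- replicate 2 (adjusted p = 0.0243, and adjusted p = 0.660 with an estimated correlation). Of 12 fatty acid synthesis genes Elovl6, an elongase gene, rose (0.92, SE 0.17) and 11 did not pass. The synthase gene Fasn (-0.49, SE 0.14) was also lower adjusted over the list alone. Of 17 heat shock genes Hspa1b alone fell over all genes, and 3 fell adjusted over the list alone. Without 1 array at a time Prc1, Gadd45a, Elovl6, Hspa1b and Cdk4 passed each time, En2 in 4 of 6 cases, Smc2 and Nnat in 3, Fen1, Hmgcs1 and Pou3f1 in 2 and Orc1 in 1, with adjusted p up to 0.182. As lists, mitosis and heat shock passed without E14 replicates 1 or 2 and the G1, primitive and visceral endoderm and immediate early lists without E14 replicate 3, the last also without Cdk4 +/- replicate 2 (adjusted p from 0.0210 to 0.0426). With an estimated correlation these had adjusted p from 0.172 to 0.510. Next to Cdk4 on chromosome 10, Tsfm, a mitochondrial translation factor gene 5 genes away, fell (-0.58, SE 0.15, adjusted p = 0.0400, passing in 1 of 6 cases without 1 array), and Tspan31, the adjoining gene, was at 0.67 (SE 0.24, adjusted p = 0.126). The other measured neighbours Ctdsp2 (0.21), Mettl1 (0.05), Arhgef25 (-0.05) and Pip4k2c (0.05) did not pass. No chromosome passed as a whole with camera (shifts from -0.09 to 0.07, smallest adjusted p = 0.418 over 20 chromosomes, smallest unadjusted p = 0.0209). Without 1 array at a time the count of 361 became 106, 116 or 521 without E14 replicates 1, 2 or 3 and 68, 341 or 76 without Cdk4 +/- replicates 1, 2 or 3, and all 16 arrays in one fit gave 35. At unadjusted p under 0.05 there were 1529 probe sets against 367 by chance, and 1831 (24.9%) had no overlap between the groups, where chance gives 10%.

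The difference between both mutations was tested as an interaction in the same fit, Abca1 +/- minus ESVJ against Cdk4 +/- minus E14. Of 7349 probe sets, 15 had a higher and 31 a lower signed log2 change in the Abca1 comparison than in the Cdk4 comparison. The largest positive differences were those of Ppan (1.32, SE 0.22), Gclm (1.31, SE 0.23), Cd99 (1.30, SE 0.24), Trim25, a ubiquitin ligase gene of antiviral signalling (1.21, SE 0.23), and Epb41l4aos (1.21, SE 0.21). The largest negative differences were those of Ddx4, a germ cell RNA helicase gene (-1.60, SE 0.32), Tbx3 (-1.48, SE 0.26), Txnip (-1.46, SE 0.19), Gm2022 (-1.46, SE 0.20) and Klf10 (-1.43, SE 0.20), with adjusted p between 0.00488 and 0.0375 for these 10 genes. Txnip, Gm2022 and Klf10 passed with each of the 12 arrays left out, and the other 7 lost their call for 6 to 8 of the 12 (adjusted p up to 0.110). By its other probe set Txnip was at -0.09, while Klf10 was at -1.72 by its other. The interferon and MHC list had a median difference of 0.37 and the pluripotency list of -0.19, each with adjusted p = 0.00504, and adjusted p = 0.539 with an estimated correlation. Of 36 pluripotency genes 2 were lower over all genes, Tbx3 and Klf4 (the latter in 2 of 12 cases without 1 array), and 9 were lower and 1 higher adjusted over the list alone. Of 18 interferon and MHC genes 0 differed over all genes and 4 were higher adjusted over the list alone. Across 5590 genes, which are not independent replicates, the changes of both comparisons correlated with Pearson's r = -0.12 and Spearman's rho = -0.15. Of the 361 probe sets changed in Cdk4 +/- cells, 133 (36.8%) went the same way in Abca1 +/- cells, against 44.4% of all probe sets. The other 9 splits of the Abca1 +/- and ESVJ arrays gave from 30.8% to 69.2% when taken to either side. Without 1 array at a time the count of 46 ranged from 5 without Cdk4 +/- replicate 3 to 93 without E14 replicate 3.

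The +/+ lines E14 and ESVJ differ in origin and in culture, which sets the background of both comparisons. Krt19 was at 2562 ± 175 in E14 against 54.5 ± 25.7 in ESVJ (SD, n = 3 per group), and Krt18 at 8613 ± 1148 against 264 ± 32.8, log2 differences of 4.96 and 4.87. Both are keratin genes of simple epithelia, and on this scale they were followed by Pmp22, a myelin protein gene (4.54), the signalling gene Wnt4 (4.45) and the muscle actin gene Acta1 (4.43). Hprt, the purine salvage enzyme gene that E14-derived sublines are known to lack, was at 61.9 ± 12.7 in E14 against 2983 ± 172 in ESVJ (SD, n = 3 per group), a log2 difference of -5.01. Gm2022 was at -3.49, D13Ertd608e at -3.26, Tcstv3, a gene of the 2-cell-like state, at -3.17 and Thumpd1, an RNA acetylation factor gene, at -3.15, with adjusted p of 2.50e-08 or less for these 10 genes. The lower signal of Krt19, Pmp22, Wnt4, Hprt and D13Ertd608e lies under 100, so the size of their difference and its rank depend on the pseudocount. With 1 and with 100, Krt19 was at 5.67 and 4.12, Wnt4 at 5.89 and 3.27 and Hprt at -5.58 and -4.25, all past the threshold. In all, 1457 probe sets were higher and 1673 lower in E14, 937 of them by 2-fold or more, around a median shift of all probe sets of -0.09 (-0.12 on the deposited scale).

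Of 36 pluripotency genes 25 were lower in E14 and 4 higher (26 and 5 adjusted over the list alone), with Nr0b1 at -1.47 (SE 0.11) and Fbxo15 at -1.62 (SE 0.14). Of 18 interferon and MHC genes 10 were higher and 1 lower (10 and 2 adjusted over the list alone), with B2m, the class I light chain gene, at 2.30 (SE 0.23) and the peptide loading gene Tapbp at 2.05 (SE 0.14). Of 13 p53 response genes 9 were higher and 2 lower by either adjustment, with the cell cycle inhibitor gene Cdkn1a at 2.07 (SE 0.17) and Mdm2, which encodes the ligase that degrades p53, at 2.26 (SE 0.23). Of 38 S phase genes 20 were lower and none higher (22 lower adjusted over the list alone), with the polymerase alpha gene Pola1 at -1.25 (SE 0.16). Of 28 feeder and fibroblast markers 13 were higher in E14 and 4 lower (13 and 5 adjusted over the list alone), with the smooth muscle genes Tagln at 2.68 (SE 0.13) and Acta2 at 2.59 (SE 0.14); E14 is the line grown without feeders. With camera 11 of 22 lists passed, none with an estimated correlation (smallest adjusted p = 0.132, 7 at unadjusted p under 0.05), and 16 with fry. Line and culture conditions change together here, so no difference belongs to either alone. The 3' BioB hybridisation control was at 554 to 762 in E14 arrays and at 239, 259 and 1314 in ESVJ replicates 1, 2 and 3. These signals differed in part with the line, so array processing is not separated from line and culture either.

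**Figure D3:**
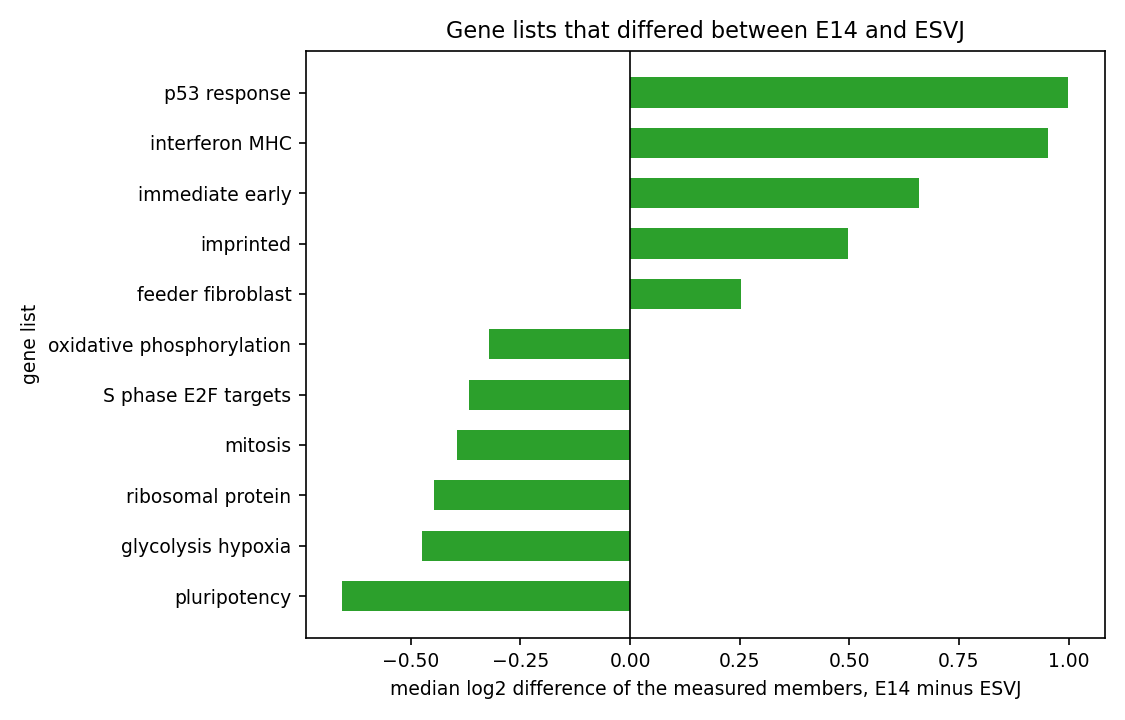
Median log2 change (x axis) of the measured members of the 11 gene lists that passed camera with a preset correlation between the +/+ lines, for E14 minus ESVJ. The pluripotency list stands at -0.66 and the interferon and MHC list at 0.95.

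The third comparison asks what the livers of mice labelled Abca1 +/- show beside those of +/+ mice. Nav2, a neuron navigator gene, rose from 69.4 ± 2.33 to 1348 ± 676 (SD, n = 2 per group, log2 3.67, adjusted p = 0.0280), the single change among 7160 probe sets. Its +/+ signal lies under 100, and its log2 change was 4.16 with a pseudocount of 1 and 3.01 with 100, past the threshold both times. Abca1 did not pass by either probe set: in the livers labelled Abca1 +/- the first was at 627 ± 102 against 314 ± 18.5 (SD, n = 2 per group), a log2 difference of 0.92 (SE 0.33, adjusted p = 0.191), higher in 2 of 2 livers. The second probe set was at 101 ± 84.2 against 217 ± 109, a log2 difference of -0.996 (SE 0.56, adjusted p = 0.366). Where these probe sets lie relative to the mutated part of the gene is not given in the sources used here, so neither tests the genotype. None of the 6 nearest measured neighbours of Abca1 passed. On one side the adjoining choline transporter gene Slc44a1 was at 1.44 (SE 0.34, adjusted p = 0.113), Tmem38b at 0.52 and Rad23b at 0.95 (SE 0.35, adjusted p = 0.207), and on the other Rnf20 was at -0.27, Mrpl50 at -0.73 and Baat at -0.43. A two-sided exact permutation test cannot go below p = 0.333 with 2 against 2 arrays.

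Genes with the smallest unadjusted p in the livers, none of which passed, were all higher in the livers labelled Abca1 +/-, around a median shift of all probe sets of 0.11. Apob, the structural protein gene of very low density lipoproteins, was at 4152 ± 570 against 752 ± 52.5 (SD, n = 2 per group), a log2 difference of 2.41 (adjusted p = 0.0984). With each of the 4 arrays left out its log2 difference lay between 2.27 and 2.55. Such a fit leaves a single liver in a group, so whether a gene passes there gives no support. Masp1, a protease gene of the lectin complement pathway, was at 2.54, the metallothionein gene Mt2 at 2.78, Rab11b, a recycling endosome GTPase gene, at 2.89 and the G protein gene Gna11 at 2.43. Pter was at 2.29, Nbr1, an autophagy receptor gene, at 2.21, Atxn2 at 2.11 and Zfp36l2, an mRNA decay factor gene, at 2.02, the last with -0.26 by its other probe set; these 8 had adjusted p = 0.101. In cholesterol transport, 0 of 27 measured genes passed over all genes and 2 were higher adjusted over the list alone, Apob and the lysosomal cholesterol transporter gene Npc1 (1.39, SE 0.33).

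By list, the ribosomal protein genes had a median of -0.69 in the livers labelled Abca1 +/- with 0.13 for the other genes (27 measured, 0 passed by either adjustment, camera adjusted p = 6.73e-08). Rps19 was at -1.76 (SE 0.43) and Rpl13a at -1.51 (SE 0.41). Oxidative phosphorylation genes had a median of -0.53 (42 measured, 0 passed by either adjustment, adjusted p = 1.16e-07), with the complex I gene Ndufb8 at -1.59 (SE 0.37). Acute phase genes had a median of 0.65 (27 measured, 0 passed over all genes, 4 higher adjusted over the list alone, adjusted p = 0.00391), with Mt2, Mt1 (2.26, SE 0.47), Serpina3n (1.86, SE 0.47) and Itih3 (1.74, SE 0.44) as the 4. Male-biased liver genes had a median of -0.49 (9 measured, 0 passed over all genes, 1 lower adjusted over the list alone, adjusted p = 0.00452), led by the steroid enzyme gene Hsd3b5 at -2.48 (SE 0.58). Hsd3b5 was at 474 and 2113 in the +/+ livers and at 125 and 190 in the livers labelled Abca1 +/-. Relative to other genes this list was at -0.70 in replicate 1 and -0.47 in replicate 2 of the latter. The gap between the +/+ livers was 0.32. Kupffer cell and macrophage genes had a median of 0.57 (15 measured, 0 passed over all genes, 1 higher adjusted over the list alone, adjusted p = 0.0452), led by the receptor gene Csf1r at 1.84 (SE 0.44). With an estimated correlation these 5 lists had adjusted p = 0.960 (ribosomal, oxidative phosphorylation, male-biased) or adjusted p = 0.973 (acute phase, Kupffer cell), and fry passed none of 33 lists.

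RNA measures and single arrays differed within the group of livers labelled Abca1 +/-. In replicate 1 the ratio of 3' to 5' signal of the actin control was 8.24, against 1.78 to 2.14 in the other 3 livers, and its Gapdh ratio was 4.10 against 0.815 to 1.13. In that array the acute phase gene Saa2 was at 35370 by 1 of its 2 probe sets, against 433 in replicate 2 and 338 and 350 in the +/+ livers. By the other probe set Saa2 was at 51420, against 1352 in replicate 2 and 1180 and 964 in the +/+ livers. Relative to other genes, the ribosomal list was at -1.42 in replicate 1 and -0.53 in replicate 2, and cholesterol synthesis genes were at -0.92 in replicate 1 and 0.97 in replicate 2. Xist, the transcript of the inactive X chromosome, was at 992 in replicate 2 and between 76.5 and 144 in the other 3 livers, and the labels do not give the sex of the animals. Whether sex contributes to the shift of the male-biased list was not tested. Without replicate 1 the acute phase list (median 0.33, adjusted p = 0.0580) and the Kupffer cell list (median 0.22, adjusted p = 0.226) no longer passed. The other 3 passed with a preset correlation, and had adjusted p = 0.752 with an estimated correlation. Cholesterol synthesis (adjusted p = 3.12e-05), female-biased (adjusted p = 0.0194) and pancreas genes (adjusted p = 0.0495) passed as well, also with adjusted p = 0.752 with an estimated correlation. Without +/+ replicate 2 the interferon and MHC, immediate early and heat shock lists passed (adjusted p = 0.0122, 0.0175 and 0.0205), with adjusted p = 0.958 with an estimated correlation. The Kupffer cell list also did not pass without +/+ replicate 1 (adjusted p = 0.262), without a filter (adjusted p = 0.0569), without cross-hybridising probe sets (adjusted p = 0.0584) or with the mean of all probe sets of a gene (adjusted p = 0.103). The count of 1 changed probe set became 82 and 27 without +/+ replicates 1 and 2, and 9 and 1653 without replicates 1 and 2 of the livers labelled Abca1 +/-; Nav2 did not pass with quantile normalization (adjusted p = 0.199) or without an intensity trend (adjusted p = 0.0933). At unadjusted p under 0.05 limma counted 1321 probe sets against 358 by chance, 3704 (51.7%) had no overlap between the groups, where chance gives 33.3%, and in simulated data 16% of changes of 1 on the log2 scale were found.

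**Figure D4:**
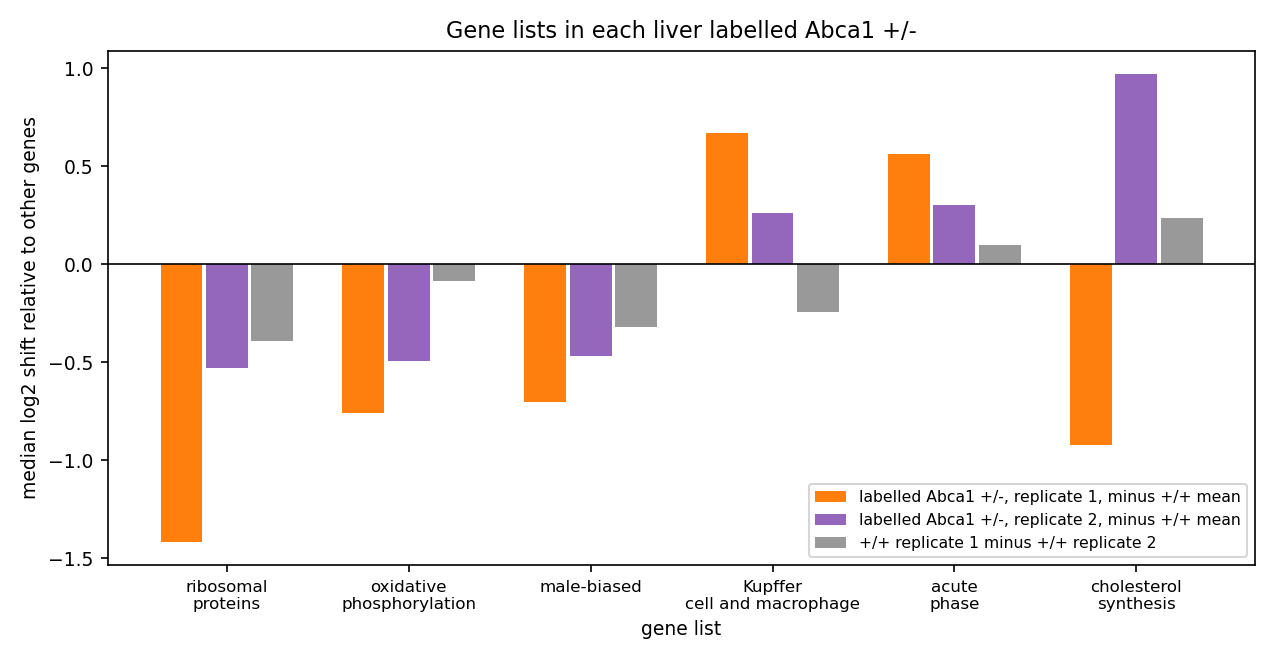
Median log2 shift of 6 gene lists relative to other genes (y axis) in each liver labelled Abca1 +/- against the mean of both +/+ livers, with the difference between both +/+ livers beside it. The ribosomal list stands at -1.42 in replicate 1 and -0.53 in replicate 2, against -0.39 between the +/+ livers.

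The last comparison sets the Abca1 change in ES cells against that in liver, in a fit of these 4 groups with 7883 probe sets. In this fit the ES arrays lend their smaller spread to the livers. The median SE of the difference was 0.36, below the 0.38 of the liver change alone, so too many probe sets may pass. The difference passed for 188 probe sets, 29 with a higher log2 change in ES cells and 159 with a higher one in liver. The median difference was -0.12 (0.01 with quantile normalization, where 55 passed). Among those with a higher change in liver were Nav2 (-3.17, SE 0.40), Lclat1, an acyltransferase gene of cardiolipin remodelling (-3.04, SE 0.62), Mt2 (-2.90, SE 0.52), Rab11b (-2.84, SE 0.49) and Apob (-2.69, SE 0.36). Among those with a higher change in ES cells, which need not be a higher level there, were the chemokine scavenger gene Ackr4 (2.07, SE 0.48), Uqcc2, an assembly factor gene of respiratory complex III (1.95, SE 0.42), the proteasome subunit gene Psma7 (1.91, SE 0.41), the autophagosome gene Map1lc3b (1.85, SE 0.43) and Itgb1bp1, a regulator of integrins (1.78, SE 0.36). Itgb1bp1 was at only 0.21 and 0.06 by its other probe sets. The differences depend in part on replicate 1 of the livers labelled Abca1 +/-, the array with the high actin and Gapdh ratios. Without it Uqcc2 was at 1.41, Psma7 at 1.38, Map1lc3b at 1.22 and Ackr4 at 2.01. Nav2 was then at -2.65, Mt2 at -2.285 and Apob at -2.55. These 10 genes had adjusted p between 0.0160 and 0.0457. Leaving out 1 of the 10 arrays ended the calls of Nav2 and Apob in 2 cases (Abca1 +/- ES replicate 3 and ESVJ replicate 3, adjusted p = 0.0582 and 0.0513). It ended those of Mt2 in 5, of Rab11b and Lclat1 in 7 and of the 5 genes with a higher change in ES cells in 8 or 9. With quantile normalization Lclat1 and these 5 genes did not pass (adjusted p from 0.0527 to 0.0918). Without ESVJ replicate 3 the count was 0. Fits without 1 liver leave a single liver in a group, so calls kept or lost there give no support.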

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

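The tests of RNA quality, of exchanged liver labels and of the hybridisation control below were chosen only after the result was seen; the splits of the arrays and the test along the difference between the +/+ lines were planned before it.

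The change differed between both ES mutations for 46 probe sets, tested as an interaction of Abca1 +/- minus ESVJ against Cdk4 +/- minus E14. Among the genes the text names, the difference was positive for Cd99 (1.30), Cdk4 (0.68), Epb41l4aos (1.21), Gclm (1.31), Ppan (1.32), Socs1 (1.20), Trim25 (1.21) and Yy1 (1.11). It was negative for Ddx4 (-1.60), Gadd45a (-0.93), Gm2022 (-1.46), Klf10 (-1.43), Klf4 (-0.92), Mtf2 (-1.24), Prc1 (-0.85), Smc2 (-1.11), Stat6 (-1.27), Tbx3 (-1.48) and Txnip (-1.46, but -0.09 by its other probe set). Of 100 drawn splits of the arrays within both lines, 3 gave 46 probe sets or more, the real one included, with 91 as the highest other. This share lies under 0.05, without correction for the other tests of a random grouping. Each line has only 10 splits, which the 100 combine, so a random grouping is not excluded for this count. The interferon and MHC list (0.37) and the pluripotency list (-0.19) also differed with a preset correlation (adjusted p = 0.539 with an estimated correlation for both), but 58 of the 100 splits gave 2 lists or more, up to 8, so a random grouping is not excluded for the lists.

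The Abca1 change differed between ES cells and liver for 188 probe sets, in a fit where the ES arrays lend their smaller spread to the livers, so too many may pass. Among named genes it was higher in ES cells for Ackr4 (2.07), Cd99 (1.77), Itgb1bp1 (1.78, but 0.21 and 0.06 by its other probe sets), Map1lc3b (1.85), Psma7 (1.91) and Uqcc2 (1.95). It was higher in liver for Apob (-2.69), Atxn2 (-1.83), Gna11 (-2.14), Lclat1 (-3.04), Masp1 (-2.65), Mt2 (-2.90), Nav2 (-3.17), Nbr1 (-2.30), Pdcd4 (-2.61), Pter (-2.53), Rab11b (-2.84), Slc44a1 (-1.51), Tle5 (-2.27) and Zfp36l2 (-1.71).

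Control probe sets, which no comparison uses, stood at more than 1.5 times the highest control array in 2 arrays, and smaller excesses were not counted. In Cdk4 +/- replicate 2 the spiked BioB transcript was at 1405 by its 3' and 2985 by its middle probe set and CreX at 19660, against at most 762, 1830 and 13070 in E14. In replicate 1 of the livers labelled Abca1 +/- the 3' to 5' ratio was 8.24 for actin and 4.10 for Gapdh, against at most 1.81 and 0.919 in the +/+ livers.

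In the livers labelled Abca1 +/-, ribosomal and oxidative phosphorylation genes were lower and acute phase genes higher as lists with a preset correlation, with no member passing over all genes and adjusted p = 0.960, 0.960 and 0.973 with an estimated correlation. If the RNA quality of replicate 1 were the whole cause, replicate 2 alone would not move beyond the gap between both +/+ livers. Replicate 2 alone stood at -0.53 for ribosomal genes (gap 0.39), -0.49 for oxidative phosphorylation (gap 0.09) and 0.30 for acute phase genes (gap 0.10), the first short of 2 times its gap. All 3 shifts exceed their gap. Without replicate 1 the medians of these lists, not taken relative to other genes, were -0.50, -0.45 and 0.33. This sets the same liver against the same +/+ livers and so adds no separate support. But as 1 liver excludes nothing, the RNA quality of replicate 1 may be a source of each. The labelled genotype, the sex of the animals, the mixed background and variation between single animals stay open as untested biological explanations. The acute phase gene Saa2 was at 35370 in replicate 1 by 1 of its 2 probe sets, against 433 in replicate 2 and 338 and 350 in the +/+ livers.

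By its first probe set, Abca1 was higher, not lower, in the livers labelled Abca1 +/-. Replicate 2, whose RNA controls resemble those of the +/+ livers, was higher by 0.76 against a gap of 0.11 between both +/+ livers, against the RNA quality of replicate 1 as the whole source, but as this is 1 liver, that stays open. An exchange of the liver labels might give the same picture, but the second Abca1 probe set stood at -0.996 (SE 0.56), the other way and within 2 SE of 0. The neighbours Slc44a1 (1.44) and Rad23b (0.95) were also higher without passing, so a difference shared by this side of the region stays open as an untested biological explanation. The position of the probe sets relative to the mutation is not given in the sources used here, and with 2 arrays per group an exchange, a probe that misses the mutation and variation between animals cannot be told apart.

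In Cdk4 +/- ES cells 361 probe sets changed, and with the arrays of high BioB signal as a block 271, against at most 116 in the other 9 splits fitted with the same block. Without these arrays 417 changed, against at most 285 in the other 9 splits of the 5 arrays left. In this comparison only Cdk4 +/- replicate 2 has a high BioB signal. The counts thus argue only against that array as the whole source, and 10 splits are too few for a share under 0.05. If the Cdk4 +/- cells had shifted along the difference between E14 and ESVJ, the change would run against that difference across genes, with separate E14 arrays for each side. The 3 ways of doing this gave correlations of -0.122, -0.183 and 0.0576 (SD 0.125). The plan asked for a negative correlation in each of the 3 ways and took any that was not negative as against the shift. The third value thus met the planned criterion against it. Departing from that plan, the test is read as undecided, since the other values were negative and the spread was wide. Such a shift may still be part of the pattern. Clonal drift between the line and its control, apart from the mutation, stays open as an untested biological explanation, since the labels name 1 line per genotype.

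For counts from 3 against 3 arrays, 10 splits are too few for a share under 0.05, and the real value stands beside the highest other: 361 against 49 for Cdk4, 2 against 0 for Abca1 and 3130 against 0 for E14 against ESVJ, where 1 split each, the real one, gave as many. The Cdk4 splits with 49, 116 and 285 probe sets all set E14 replicates 1 and 2 apart from E14 replicate 3 and Cdk4 +/- replicates 1 and 3. In those with 49 and 116, Cdk4 +/- replicate 2 stood with E14 replicates 1 and 2, so both groups were divided. The source of this structure was not tested. For gene lists the real and the highest other value were 2 against 8 for Cdk4 (7 splits gave as many), 0 against 2 for Abca1 (all 10) and 11 against 10 for E14 against ESVJ (1), and for chromosomes 0 against 0 for both mutations (all 10). The absolute correlation between both mutation effects was 0.12, reached by 27 of 100 splits within both lines with 0.26 as the highest other, so a random grouping is not excluded for it.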

How the results depend on the processing

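The block and the omission of the arrays of high BioB signal were chosen only after the data were seen. Of 253 alternative values of the main results, 180 kept their direction and their side of the threshold or stayed within a factor of 1.5, 71 moved, 2 became stronger, 0 became weaker and 0 reversed. Counts could by rule only stay or move, so they could not become weaker or reverse. Of the tested levels of Abca1 and Cdk4, only the Cdk4 fall passed at the outset and could become weaker. Single genes and lists named in the text held less well: without 1 array, calls became weaker in 64 of 100 values for the tissue interaction, 47 of 120 for the ES interaction, 20 of 117 for Cdk4 and 3 of 20 for liver lists. Under the other settings this was so in 19 of 68, 7 of 69, 6 of 134 and 8 of 45, and in 2 of 22 for Cdk4 lists and 2 of 70 for liver genes. The Cdk4 fall stayed past the threshold under all 11 other settings and each array left out (-0.67 to -0.59 without 1 array), and the E14 against ESVJ count stayed within a factor of 1.5 (2529 to 2857 without 1 array). Otherwise the cause was not tested, except where arrays were left out or pooled, which changes the samples and the degrees of freedom. Without a filter the counts were 1 (Abca1 ES), 196 (Cdk4 ES), 16 (ES interaction), 3 (liver) and 75 (tissue interaction), 5 lists passed for Cdk4 and the effect correlation was -0.0660. With a filter of 200, 1 probe set passed for Abca1 ES. On the deposited scale 23 passed for the ES interaction and 2 in liver, and the correlation was -0.0611. With quantile normalization 0 passed in liver and 55 for the tissue interaction, with 5 lists for Cdk4. Without an intensity trend 227 passed for Cdk4, 19 for the ES interaction and 0 in liver. With only the 2 compared groups 1 passed for Abca1 and 174 for Cdk4. With all 16 arrays in one fit, where ES arrays lend their smaller spread to the livers, 0 passed for Abca1 ES, 35 for Cdk4 and 1970 in liver, and the Abca1 difference in liver (0.92) passed. With an estimated correlation 0 lists passed for Cdk4 and 0 in liver. With the BioB block 1 probe set passed for Abca1 ES and 5 lists for Cdk4; without the 3 arrays of high BioB signal these were 4 and 5. Leaving out 1 array at a time gave 1 to 1 for Abca1 ES, 68 to 521 for Cdk4, 5 to 93 for the ES interaction, 9 to 1653 in liver and 0 to 2007 for the tissue interaction. Lists then ranged from 0 to 2 (Abca1 ES), 2 to 7 (Cdk4) and 4 to 8 (liver), the correlation from -0.184 to -0.0254 and the Abca1 difference in liver from 0.76 to 1.08, past the threshold without replicate 2 of the livers labelled Abca1 +/-. A group left with 1 array is assumed to vary like the others in its fit. Of the 361 probe sets, between 68 and 290 were called again without 1 array. No paired analysis was possible because the labels give no replicate numbers that would pair the samples. Signal over background limits Abca1, whose ES signals lie near the filter.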

Other observations

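The values below are descriptions, and none of them was tested beyond what is stated.

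In the livers, endothelial genes, which no comparison above describes, had a median of 0.35 in the livers labelled Abca1 +/- with all 12 measured members above 0 (camera adjusted p = 0.129). The receptor genes Flt4 (1.56, SE 0.37) and Cdh5 (1.63, SE 0.43) were the 2 that were higher adjusted over the list alone, and none passed over all genes. Of 15 circadian genes, Bhlhe40, a clock repressor gene, was at 1.63 (SE 0.35) and the period gene Per1 at 1.48 (SE 0.46), with a list median of 0.41 (adjusted p = 0.268), and the hour of tissue collection is not given in the sources used here. Hepatocyte genes had a median of -0.19 (24 measured, adjusted p = 0.376). Cholesterol synthesis genes had a median of 0.14 (17 measured, adjusted p = 0.726), with Hmgcs1 at 1.36 (SE 0.37) and the lanosterol synthase gene Lss at 1.20 (SE 0.34) as the 2 higher adjusted over the list alone, and the 2 arrays of the group stood on opposite sides of the +/+ livers.

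In the +/+ ES lines, 12 of 22 immediate early genes were higher in E14 and 2 lower, with the matricellular gene Ccn1 at 2.26 (SE 0.15) and Klf6 at 2.02 (SE 0.17). Of 23 imprinted genes 12 were higher and 2 lower, with the growth factor gene Igf2 at 2.97 (SE 0.12) and Gnas at 1.54 (SE 0.14). Of 23 glycolysis and hypoxia genes 16 were lower and 3 higher, with the phosphofructokinase gene Pfkp at -2.35 (SE 0.20) and Bnip3, a mitophagy receptor gene, at -2.08 (SE 0.20). Of 27 ribosomal protein genes 15 were lower and none higher. These 4 lists passed with a preset correlation (adjusted p = 6.74e-04, 0.00829, 0.00775 and 4.13e-04) and did not with an estimated correlation (adjusted p = 0.1498, 0.132, 0.309 and 0.445).

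Among probe sets called in the Cdk4 comparison without 1 E14 array, 67.9%, 75.9% and 46.6% went against the difference of that left-out array from ESVJ, where 56.0%, 57.9% and 49.3% of all probe sets did. In Cdk4 +/- cells Abca1 was at 298 ± 47.6 against 219 ± 24.4 in E14 (SD, n = 3 per group, log2 0.39, adjusted p = 0.276) by its first probe set and at 102 ± 28.8 against 29.7 ± 17.4 by its second, which lies below the signal filter (log2 1.13, 95% interval 0.57 to 1.70, two-sided exact permutation p = 0.1).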
